A study of Mus musculus with 31 samples.

How the data were processed

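The series holds 31 mouse libraries made by high-throughput genome-wide translocation sequencing (HTGTS), in which DNA next to a fixed bait break is amplified and sequenced so that each junction between the bait and another broken end (the prey) is read. The labels name 3 assays in 4 genotypes, which gives 12 groups. Coding joins and signal joins were read on pMX-INV, an inversion substrate for V(D)J recombination integrated in the genome of v-abl transformed B cells. Per the labels' protocols, those cells were treated with STI571 at 3 µM for 4 days, which arrests them in G1 and induces the RAG recombinase. Class switch recombination (CSR) was read from a bait in the switch region Sμ of splenic CD43-negative B cells grown for 4 days with anti-CD40 at 1 µg/mL and IL-4 at 20 ng/mL. Genotypes were wild type, PQR (homozygous for a mutation of a phosphorylation-site cluster of DNA-PKcs), Xlf-/- and the PQR Xlf-/- double mutant.

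The deposited files are tables of junctions, 1 set of sheets per library, plus sheets that pool the libraries of a genotype. Bowtie2, mm9 and mm10 are named in the submitters' processing notes, with no version and no role. The filters that made the junction lists, including any removal of duplicate molecules, are not given in the sources used here. The authors' counts are whole numbers of junctions per substrate position, per chromosome, or per switch region and strand, with no normalization, per the file headers and values. Positions of substrate junctions are in bp along the substrate, per the file headers, with the prey strand given as a sign. The fixed ends of the substrate were read from the authors' deposited deletion sheets. The bait coding end lies at position 1947 and the prey coding end at 2816, and the signal ends lie at 1946 and 2815. Switch-region positions lie on chromosome 12. They did not overlap the place of Ighg1 in the GRCm38.p6 gene table, so of the builds named they were taken to be in mm9. Prey positions on chromosome 6 from the coding-join assay piled up at the Jκ segments of the same table, so those were taken to be in mm10.

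A coding join was a junction with prey on the plus strand at or beyond the prey coding end, with 10 bp of slack. A signal join was a junction with prey on the minus strand up to the prey signal end, with the same slack. Loss was counted from the fixed end to the junction, 0 bp where the alignment ran past it, and loss of more than 20 bp set the main threshold. A signal join was called precise when neither end had lost a bp, whether or not bases were inserted. A junction lay at the expected coding ends when both ends had lost at most 100 bp. Microhomology is the number of bases shared by the bait and prey alignments. It was called from 2 bp in coding joins and from 4 bp in switch junctions, over all junctions of Sγ1 and Sε with a stated gap. Inserted bases count as no microhomology. In CSR libraries, minus-strand prey is the deletional orientation and plus-strand prey the inverted one.

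The table with gaps for each coding join was not used here for library 2 of Xlf-/-, so coding microhomology there has n = 1. For signal joins, gaps came only from sheets pooled per genotype, and those leave out the most frequent precise alignment. The 5 planned tests of signal-join microhomology were therefore not run, and the authors' pooled values are given without an SD or a test. A summary sheet with 31 columns of per-sample values under numbers that the labels do not tie to samples was not used.

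Each share was computed per library and averaged per genotype with its SD. Pairs of genotypes were compared by a two-sided exact permutation test of the difference of means. Every assignment of library labels was enumerated. The effect of each gene was also tested over all libraries of an assay, permuting labels within the strata of the other gene and averaging the 2 within-stratum differences. Benjamini-Hochberg adjustment was made within each assay and kind of test. For shares, a call in the alternatives means an unadjusted exact p under 0.05, and adjusted values are given beside the main results. Usage of positions was compared on counts of junctions per bin: 10 bp within 100 bp of the expected ends, 100 bp elsewhere on the substrate, and 500 bp by orientation across IgH. edgeR's quasi-likelihood test was run on these counts as deposited, with all genotypes of an assay in 1 fit, library size equal to all junctions of the library, filterByExpr with a minimum of 10 junctions, and a Benjamini-Hochberg adjusted p threshold of 0.05. On simulated bins with 20% changed 4-fold in the comparison of PQR with wild type, over 20 draws, the test recovered 75.6% of the changed bins in the coding-join assay (38 bins), 16.2% in the signal-join assay (59 bins) and 92.0% in the CSR assay (116 bins). Wrong calls were 0.820%, 0% and 2.31% of all calls. The simulated means were taken over all genotypes of the assay, with 1 dispersion for all bins. Bins used mainly without XLF were thus drawn with more junctions than wild type and PQR have there. For such bins the recovery may be too high for the real comparison.

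The items to be named were fixed before the data were examined: the coding and signal ends, Sμ, Sγ1, Sε and the rest of IgH, the 5 bins with the largest fold in each direction per comparison among those past the threshold, and the 3 most used positions of each assay. Any other class is said to have been chosen after its values were seen. Alternatives covered loss thresholds of 10 and 50 bp, a tolerance of 3 bp for precise joins, other microhomology minimums, junctions without insertions, other denominators, distinct positions, pooled junctions, a logit scale, the authors' own deletion sheets, TMM scaling, DESeq2, no count filter, bins of 2 times the width, the replicate number as a block, and leaving out each library. Alternatives added after seeing the data left out signal joins with far bait ends, took gaps over all IgH junctions, kept only 1 sequencing run, or added the run as a covariate.

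Sequencing runs were read from the read names and numbered. Run 1 held 5 of the 9 coding-join libraries (1 wild type, 2 PQR, 1 Xlf-/- and 1 PQR Xlf-/-) and 8 of the 12 CSR libraries (1, 2, 2 and 3). In fits within run 1 a lone library is assumed to vary like the other groups. The run is not given in the sources used here for 1 coding-join library and for all 10 signal-join libraries. Replicate libraries were compared by chi-square over bins. Each pair differed by more than sampling noise over bins except coding-join PQR libraries 1 and 2. Over the chromosomes of prey outside the substrate, each pair of the substrate assays differed except the wild-type pair, with a chi-square of 28.1 on 19 degrees of freedom for coding joins and 17.8 on 20 for signal joins. Every library was kept as its own replicate, which for wild type rests on the bins alone. The chi-square treats junctions as independent, and separate libraries of 1 line could differ over bins too. It therefore does not show that replicates are independent. Same-numbered signal-join libraries with and without XLF deviated together (correlations 0.395 for wild type with Xlf-/-, where centring 2 libraries makes both pairs equal, and 0.473, 0.196 and 0.293 for PQR with the double mutant), with no shared source given in the labels, so the paired value is given beside that XLF effect. Nothing in the labels says which libraries came from separate mice or cell lines, so p-values measure only the spread between these libraries, which may be technical. Junctions without molecular identifiers are not independent molecules, so intervals and limits for a count of 0 (3 counts) cover counting error only. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0 were used.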

Results

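DNA-PKcs and XLF both act in non-homologous end joining, the pathway that seals the breaks of V(D)J recombination and of class switching. The series asked whether XLF hides a need for the PQR phosphorylation sites of DNA-PKcs at chromosomal breaks, by reading junctions in wild-type, PQR, Xlf-/- and PQR Xlf-/- B cells. For coding joins there were 2 wild-type, 3 PQR, 2 Xlf-/- and 2 PQR Xlf-/- libraries, with 907 to 5118 substrate junctions each and 19312 in all. Depth differed by genotype in that assay: 907 to 1504 in wild type, 945 to 1291 in PQR, 2086 to 2462 in Xlf-/- and 3979 to 5118 in PQR Xlf-/-. For signal joins there were 2, 3, 2 and 3 libraries in the same order, with 12444 to 41268 substrate junctions each and 237072 in all. For class switching there were 3, 2, 4 and 3 libraries, with 3817 to 24920 junctions each and 156766 in all. Wild-type CSR libraries held 4689, 14119 and 3817 junctions. In the substrate assays, the 2 wild-type libraries shared a leading chromosome outside the substrate, and so did the 2 Xlf-/- libraries apart from chromosome 6, so neither pair is shown to come from separate cell lines.

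Coding ends are the hairpin-sealed ends that RAG leaves next to the V, D and J segments, and their joins normally lose a few bp. In wild-type cells the median loss was 8.50 bp ± 0.707 (SD, n = 2) at the bait coding end and 6.50 bp ± 0.707 (SD, n = 2) at the prey coding end. In Xlf-/- cells it was 19.0 bp ± 1.41 (SD, n = 2) and 18.0 bp ± 2.83 (SD, n = 2). More than 20 bp was lost at the prey end in 16.4% ± 6.42 (SD, n = 2) of wild-type coding joins and 46.2% ± 5.34 (SD, n = 2) of Xlf-/- coding joins. At the bait end the shares were 21.8% ± 3.27 (SD, n = 2) and 44.6% ± 4.89 (SD, n = 2). With the 4 genotypes together, loss of XLF raised the share by 36.7 points at the prey end and 34.7 points at the bait end. Both gave the smallest p that the exact two-sided permutation test allows, p = 0.0167, with an adjusted p of 0.0444 over 8 tests. All 4 Xlf-deficient libraries lay above all 5 others. Between Xlf-/- and wild type alone the differences were 29.8 and 22.8 points, and 2 libraries against 2 cannot go below exact permutation p = 0.333. Within run 1 the XLF effects were 31.6 and 32.4 points, where the smallest p allowed is 0.167. Without PQR library 1, 2 or 3 the smallest p allowed rose to 0.0556, with effects of 35.9, 36.5 and 37.6 points at the prey end and 34.4, 35.6 and 34.0 points at the bait end. Loss had no upper limit, so distant plus-strand prey counts as prey-end loss. Plus-strand bins 3116 to 3215, 3316 to 3415 and 3416 to 3515 held 26, 38 and 45 wild-type junctions. Wild-type coding joins with such loss numbered 336. In Xlf-/- those bins held 44, 26 and 50, beside 1441 coding joins with such loss.

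With XLF present, coding-end loss in PQR cells did not differ from wild type by more than the spread between libraries. The prey end lost more than 20 bp in 17.0% ± 3.37 (SD, n = 3) of PQR coding joins and the bait end in 18.8% ± 3.40 (SD, n = 3). Differences from wild type were 0.617 points (exact two-sided permutation p = 1) and -3.02 points (p = 0.4), where the smallest p allowed is 0.1. The first changed sign without wild-type library 2 (-3.92 points) and without PQR library 3 (-1.20 points). In the double mutant the shares were 60.5% ± 5.14 (SD, n = 2) at the prey end and 65.4% ± 2.85 (SD, n = 2) at the bait end. They were 14.3 and 20.8 points above Xlf-/-, with every double-mutant library above every Xlf-/- library. The exact two-sided permutation p was 0.333, the smallest that 2 against 2 can give. The median loss in the double mutant was 30.5 bp ± 2.12 (SD, n = 2) at the bait end and 28.5 bp ± 3.54 (SD, n = 2) at the prey end. Averaged over both XLF states, the PQR effect was 7.48 points at the prey end (exact two-sided permutation p = 0.167, adjusted p = 0.222) and 8.90 points at the bait end (p = 0.283, adjusted p = 0.324). Whether the PQR effect on these shares differed between the XLF states was not tested on the shares themselves.

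Fewer substrate junctions of Xlf-deficient cells fell at the expected coding ends. The share was 76.0% ± 9.14 (SD, n = 2) in wild type, 70.1% ± 1.20 (SD, n = 3) in PQR, 61.7% ± 2.55 (SD, n = 2) in Xlf-/- and 58.4% ± 1.22 (SD, n = 2) in PQR Xlf-/-. The XLF effect was -13.0 points (exact two-sided permutation p = 0.0167, adjusted p = 0.0444 over 8 tests, all 4 Xlf-deficient libraries below all 5 others), and within run 1 it was -9.90 points (p = 0.167, the smallest allowed). It was -13.3, -13.0 and -12.7 points without PQR library 1, 2 or 3 (exact permutation p = 0.0556 each, the smallest allowed) and -12.1 points without Xlf-/- library 1 (p = 0.0667). The PQR effect was -4.58 points (exact permutation p = 0.0667), and -7.81 points with p = 0.0417 without wild-type library 1. The PQR difference from wild type was -5.93 points (exact permutation p = 0.3) and turned to 0.531 points without wild-type library 2.

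Microhomology of 2 bp or more was found in 5.19% ± 0.251 (SD, n = 2) of wild-type coding joins, 7.72% ± 1.61 (SD, n = 3) in PQR, 16.9% in the 1 Xlf-/- library with gaps (233 of 1382 coding joins) and 12.1% ± 1.72 (SD, n = 2) in PQR Xlf-/-. The XLF effect was 8.05 points, with p = 0.0333, the smallest the exact two-sided permutation test allows, and it did not pass after adjustment (0.0667 over 8 tests). Among coding joins without inserted bases the XLF effect was 0.233 points (exact permutation p = 0.9). With a minimum of 4 bp it was 1.22 points (exact permutation p = 0.0667). Within run 1 it was 9.13 points, where no p under 0.05 is possible. Without any 1 library it lay between 7.44 and 8.66 points, where again no p under 0.05 is possible. The PQR effect was -1.09 points (exact permutation p = 0.767). Inserted bases, a class chosen after its values were seen, were present in 78.8% ± 0.333 (SD, n = 2) of wild-type coding joins, 63.1% ± 4.32 (SD, n = 3) in PQR, 32.4% in the 1 Xlf-/- library and 41.5% ± 4.29 (SD, n = 2) in PQR Xlf-/-. The XLF effect on insertions was -34.0 points (exact two-sided permutation p = 0.0333, adjusted p = 0.0800 over 36 tests). All 3 PQR libraries lay below both wild-type libraries, by 15.7 points on average (exact permutation p = 0.1, the smallest allowed).

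**Figure D1:**
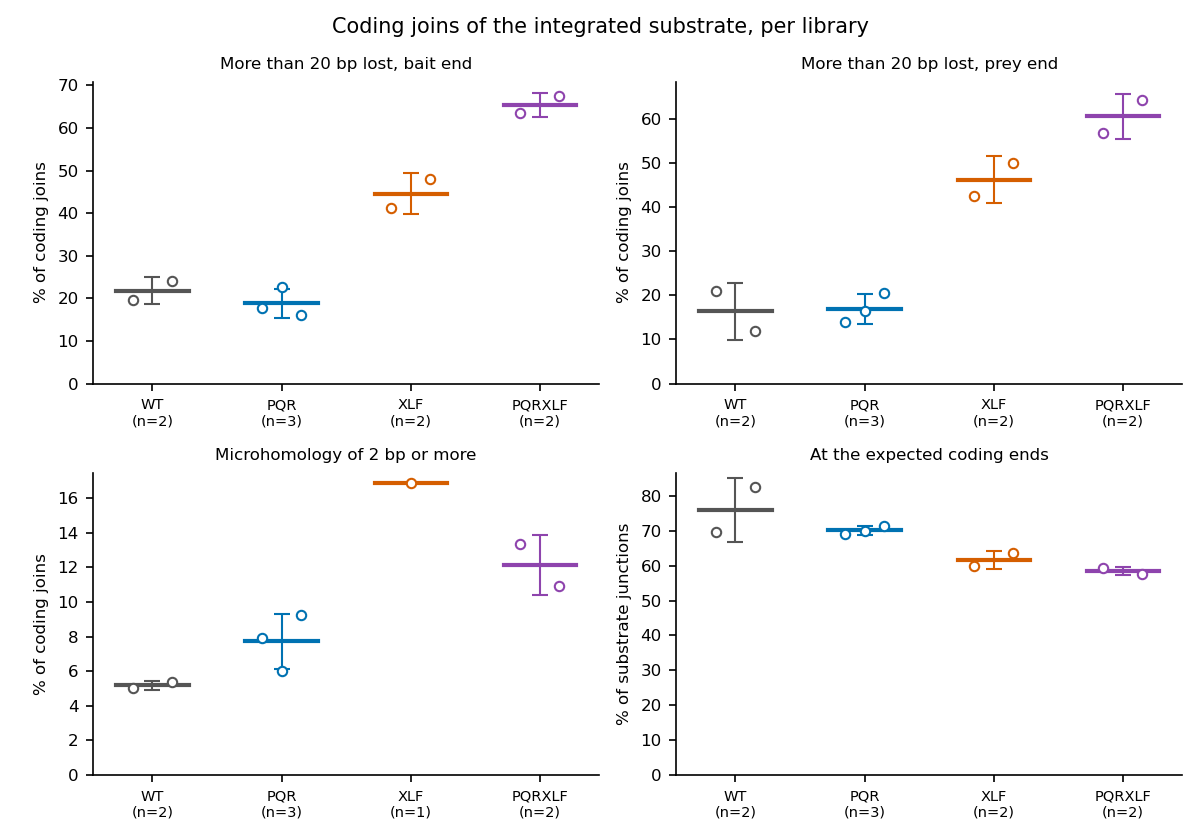
Shares of coding joins, or of substrate junctions in the last panel, per library in percent; circles are libraries, bars are genotype means and whiskers are SD (none at n = 1). All Xlf-deficient libraries lie above the others for both end-loss panels, with double-mutant means of 65.4% at the bait end and 60.5% at the prey end.

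By position, junctions moved away from the prey coding end and toward the far side of the bait cut when XLF was missing. The plus-strand bin 2816 to 2825, at the prey coding end, held 32.3% of wild-type and 12.6% of Xlf-/- substrate junctions (log2 fold -1.35, edgeR adjusted p = 1.1e-09). The bin 2806 (10 bp) on the same strand held 19.4% and 4.52% (log2 fold -2.10, edgeR adjusted p = 1.4e-15). Minus-strand prey just across the bait cut rose, from 0.122% to 2.80% in the 10 bp bin from 1937 (log2 fold 4.44, edgeR adjusted p = 2.0e-08) and from 0.0997% to 2.57% in bin 1907 to 1916 (log2 fold 4.33, edgeR adjusted p = 3.9e-09). In all, 24 of 38 bins differed between Xlf-/- and wild type, 20 higher and 4 lower. The count was 18 (10 higher, 8 lower) with TMM scaling, 11 (7 higher, 4 lower) with DESeq2 and 15 without wild-type library 1. The most used single positions were plus-strand 2814 and the 2 after it. Position 2814 took 10.8% ± 0.665 (SD, n = 2) of wild-type substrate junctions, 6.81% ± 0.556 (SD, n = 3) in PQR, 1.64% ± 0.254 (SD, n = 2) in Xlf-/- and 1.30% ± 0.229 (SD, n = 2) in PQR Xlf-/-.

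In the double mutant, 6 bins across the bait cut, from 1867 to 1926 on the minus strand, gained further on Xlf-/-. Of these, bins 1867 to 1876 and 1917 to 1926 passed narrowly (edgeR adjusted p = 0.046 and 0.049). The 2 bins nearest the cut did not pass the test (log2 fold 0.15 and -0.18). Bin 1897 to 1906 on the minus strand rose from 1.37% to 5.73% (log2 fold 2.05, edgeR adjusted p = 1.5e-05), and bin 1887 to 1896 from 0.895% to 3.72% (log2 fold 2.05, edgeR adjusted p = 0.00026). Farther plus-strand prey fell, as in bin 3416 to 3515, from 1.09% to 0.152% (log2 fold -2.73, edgeR adjusted p = 0.00027, not called by DESeq2). Between the double mutant and Xlf-/-, 15 of 38 bins differed (7 higher, 8 lower). The count was 12 (7 higher, 5 lower) with TMM scaling, 11 (10 higher, 1 lower) with DESeq2, 6 without Xlf-/- library 1 or without double-mutant library 2, 9 without double-mutant library 1, and 23 (12 higher, 11 lower) with the run as a covariate, where Xlf-/- keeps 1 library. Between PQR and wild type, 3 of 38 bins differed (2 higher, 1 lower). They were minus-strand 2876 to 2885 (log2 fold 2.14, edgeR adjusted p = 0.0071), minus-strand 2806 (10 bp) (log2 fold 1.10, edgeR adjusted p = 0.0071) and plus-strand 2806 (10 bp) (log2 fold -0.59, edgeR adjusted p = 0.038). That count was 2 with TMM scaling (1 higher, 1 lower) and with DESeq2 (0 higher, 2 lower), 0 without wild-type library 2 or PQR library 2, and 1 without PQR library 1. With the run as a covariate it was 7 (2 higher, 5 lower), and within run 1 it was 5 (1 higher, 4 lower), but both rest on 1 wild-type library, assumed to vary like the PQR libraries.

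The PQR effect on position differed with XLF status in 2 of 38 bins. Minus-strand bin 2806 (10 bp), where the bait coding end is joined to the other signal end, held 2.79% of wild-type, 6.30% of PQR, 5.62% of Xlf-/- and 2.32% of PQR Xlf-/- junctions (difference of log2 folds -2.38, edgeR adjusted p = 5.1e-07). Minus-strand bin 1047 to 1146 held 1.41%, 1.19%, 0.493% and 0.00977% (difference of log2 folds -4.65, edgeR adjusted p = 0.0049), the last value resting on 1 junction. The count was 4 (2 higher, 2 lower) with TMM scaling, and 6 (6 higher, 0 lower) with DESeq2, which called neither of these bins. It was 7 with the run as a covariate, 0 without double-mutant library 2, 1 without Xlf-/- library 2 or double-mutant library 1, and 4 without wild-type library 2.

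The ends of the substrate also formed joins other than coding and signal joins, classes chosen after their values were seen. An end rejoined across its own cut with no base lost or inserted restores the uncut substrate, which is not a junction. Joins back across a cut therefore cover only rejoining that altered the sequence. How often ends rejoined in all cannot be read from them. Coding ends joined back across their own cut in 1.07% ± 0.199 (SD, n = 2) of wild-type, 1.17% ± 0.288 (SD, n = 3) of PQR, 10.5% ± 2.01 (SD, n = 2) of Xlf-/- and 23.5% ± 3.03 (SD, n = 2) of PQR Xlf-/- substrate junctions. The XLF effect was 15.8 points (exact two-sided permutation p = 0.0167, the smallest allowed, adjusted p = 0.0561 over 36 tests). The double mutant lay 13.0 points above Xlf-/- (exact permutation p = 0.333, the smallest allowed). From the signal-end bait such joins were 0.225% ± 0.155 (SD, n = 2), 0.118% ± 0.0233 (SD, n = 3), 0.145% ± 0.0203 (SD, n = 2) and 1.07% ± 0.550 (SD, n = 3) in the same order. There Xlf-/- differed from wild type by -0.0797 points (exact permutation p = 1), and the XLF effect was 0.434 points (exact permutation p = 0.0667). Hybrid joins, coding end to signal end, made up 1.72% ± 0.372 (SD, n = 2), 0.918% ± 0.0923 (SD, n = 3), 9.40% ± 3.10 (SD, n = 2) and 11.2% ± 2.81 (SD, n = 3) of substrate junctions from the signal-end bait, in the same order. Their XLF effect was 8.97 points (exact two-sided permutation p = 0.0167, the smallest allowed, adjusted p = 0.0561). From the coding-end bait, hybrid joins were at 4.14% ± 2.89 (SD, n = 2), 8.03% ± 1.84 (SD, n = 3), 11.9% ± 2.23 (SD, n = 2) and 5.85% ± 1.83 (SD, n = 2), with an XLF effect of 2.79 points (exact permutation p = 0.367) and a PQR effect of -1.08 points (p = 0.633).

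**Figure D2:**
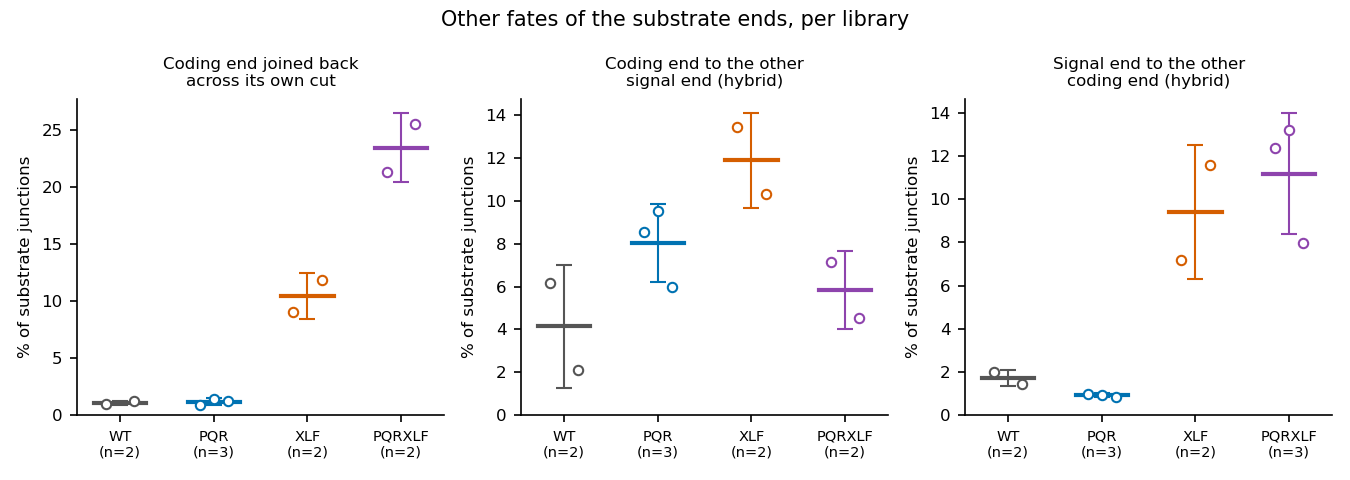
Other joins of the substrate ends per library, as percent of substrate junctions; circles are libraries, bars are genotype means and whiskers are SD. The share of coding ends joined back across their own cut has means of 1.07% in wild type, 10.5% in Xlf-/- and 23.5% in the double mutant. Rejoining that leaves the sequence unaltered is not seen.

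Signal ends are the blunt ends that carry the recombination signals and are normally joined without loss. Precise signal joins, with no bp lost at either end, were 84.0% ± 6.95 (SD, n = 2) of wild-type and 79.7% ± 2.59 (SD, n = 3) of PQR signal joins. They were 48.5% ± 10.0 (SD, n = 2) in Xlf-/- and 11.8% ± 2.16 (SD, n = 3) in PQR Xlf-/-. The median loss was 0 bp at both signal ends in every wild-type and PQR library. In the double mutant it was 10.3 bp ± 1.53 (SD, n = 3) at the bait end and 9.67 bp ± 1.53 (SD, n = 3) at the prey end. The XLF effect on precise joins was -51.7 points, with the smallest p that the exact two-sided permutation test allows (p = 0.0167, adjusted p = 0.0444 over 4 tests), and all 5 Xlf-deficient libraries lay below all 5 others. With libraries of the same replicate number paired, the XLF effect was again -51.7 points, with an exact sign-flip p of 0.0625, the smallest that 5 pairs allow. The PQR effect was -20.5 points (exact two-sided permutation p = 0.03, adjusted p = 0.0444).

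Within Xlf-deficient cells, the share of precise joins differed by -36.7 points between the double mutant and Xlf-/-, and all 3 double-mutant libraries lay below both Xlf-/- libraries (exact two-sided permutation p = 0.1, the smallest allowed). Within XLF-proficient cells, PQR differed from wild type by -4.33 points (exact permutation p = 0.5), by 0.589 points without wild-type library 1, and by 0.0355 points with up to 3 bp of loss allowed. Far bait ends, below the lowest bait end in the pooled sheets, were left out in an alternative chosen after seeing the data. These joins are never precise, and they were unequally common among genotypes, so leaving them out shifts the shares by construction. Precise joins were then 94.7% ± 0.419 (SD, n = 2) in wild type, 84.2% ± 1.54 (SD, n = 3) in PQR, 53.7% ± 8.85 (SD, n = 2) in Xlf-/- and 12.1% ± 2.22 (SD, n = 3) in PQR Xlf-/-. PQR then differed from wild type by -10.5 points, with all 3 PQR libraries below both wild-type libraries (exact permutation p = 0.1, the smallest allowed). The PQR effect over all signal joins lost its call when any of 7 libraries was left out. It was -18.1 points (exact permutation p = 0.075) without wild-type library 1 and -19.9 points (p = 0.05) without PQR library 3. It was -17.0 and -24.1 points (exact permutation p = 0.075) without Xlf-/- library 1 or 2, and -20.2, -21.2 and -20.2 points (p = 0.0833) without double-mutant library 1, 2 or 3. With joins of up to 3 bp lost still called precise, the shares were 86.7% ± 7.17 (SD, n = 2), 86.8% ± 2.27 (SD, n = 3), 56.0% ± 11.6 (SD, n = 2) and 14.3% ± 2.39 (SD, n = 3), and the PQR effect was -20.9 points (exact permutation p = 0.06).

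Loss of more than 20 bp was seen in 11.8% ± 7.08 (SD, n = 2) of wild-type signal joins, 7.44% ± 2.10 (SD, n = 3) in PQR, 15.4% ± 6.78 (SD, n = 2) in Xlf-/- and 38.5% ± 4.58 (SD, n = 3) in PQR Xlf-/-. The XLF effect was 17.4 points (exact two-sided permutation p = 0.0333, adjusted p = 0.0444 over 4 tests), and the same with replicate numbers paired (exact sign-flip p = 0.0625, the smallest allowed). It was 14.8 points without wild-type library 1 (exact permutation p = 0.0667), 16.8 points without PQR library 2 (p = 0.05), 15.0 points without Xlf-/- library 2 (p = 0.0667), and 3.83 points at a threshold of 50 bp (p = 0.233). Xlf-/- alone lay 3.69 points above wild type (exact permutation p = 0.667), and below it without wild-type library 1 (-1.32 points) or Xlf-/- library 2 (-1.11 points). The double mutant lay 23.0 points above Xlf-/- (exact permutation p = 0.1, the smallest allowed). The PQR effect was 9.35 points (exact permutation p = 0.15). PQR against wild type was -4.31 points (exact permutation p = 0.4), and 0.693 points without wild-type library 2. Joins with far bait ends were 11.3% ± 6.95 (SD, n = 2), 5.36% ± 2.56 (SD, n = 3), 9.89% ± 3.79 (SD, n = 2) and 2.36% ± 0.394 (SD, n = 3) of signal joins. All of these count as loss of more than 20 bp. Without them, such loss was seen in 0.564% ± 0.187 (SD, n = 2) of wild-type, 2.18% ± 1.92 (SD, n = 3) of PQR, 6.24% ± 3.59 (SD, n = 2) of Xlf-/- and 37.0% ± 4.80 (SD, n = 3) of PQR Xlf-/- signal joins. That removes counted joins, at rates that differ by genotype. Tests of these shares are given with the alternatives to the processing, and no conclusion is drawn from them. The authors' sheets pooled per genotype leave out the main precise alignment. For wild type, PQR, Xlf-/- and PQR Xlf-/- they held 6699, 9429, 21117 and 51704 joins. Signal joins in all numbered 44180, 56922, 52846 and 59444. Of the sheet joins, 2.48% (166), 18.2% (1717), 34.3% (7242) and 38.5% (19898) shared 2 bp or more. Inserted bases were present in 83.3% (5578), 58.7% (5533), 29.9% (6305) and 26.7% (13807). The part left out differs by genotype, so these percentages are not shares of all signal joins. Differences between them may come from that part. These pooled values carry no test.

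**Figure D3:**
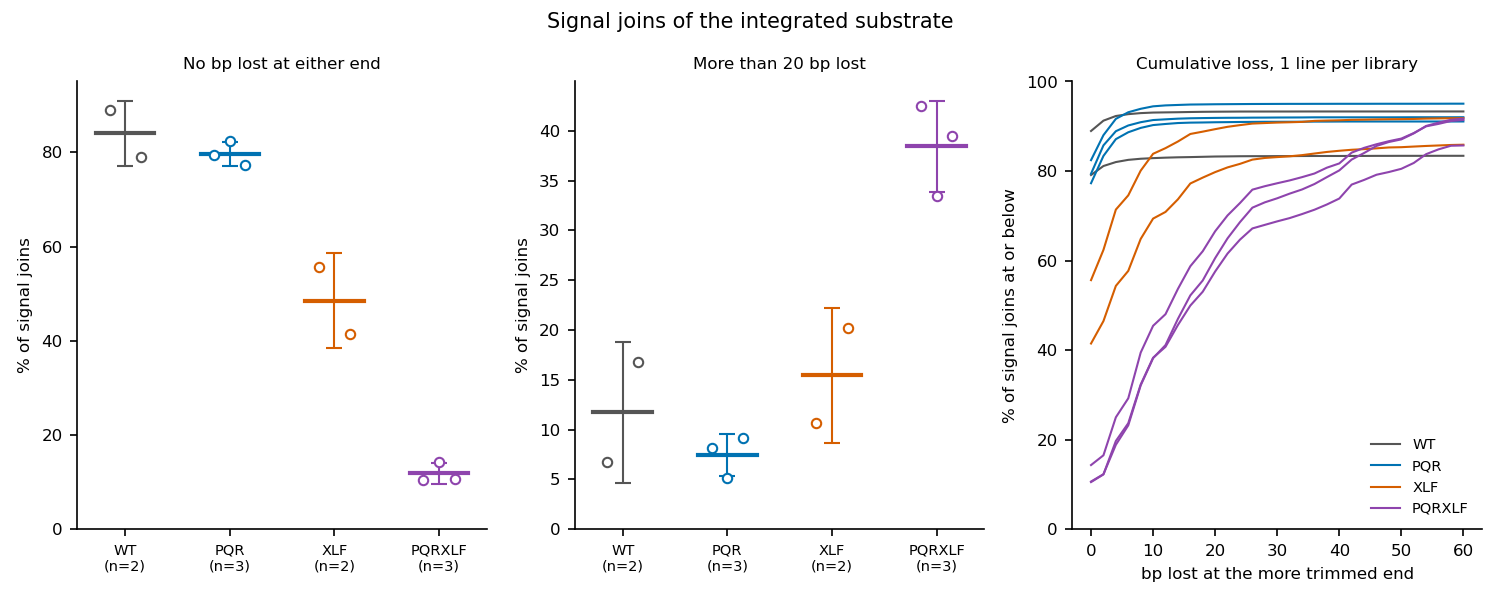
Signal joins with no bp lost and with more than 20 bp lost, per library in percent (circles; bars are means, whiskers SD), and the cumulative percent of signal joins by bp lost at the more trimmed end, 1 line per library. Double-mutant libraries hold 10.5 to 14.3% precise joins, below the 41.5 to 55.6% of Xlf-/- libraries.

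Counting by position uses the same junctions as the share of precise joins, so it is a second view of that loss and not separate evidence. The edgeR p-values rest on a model of the same libraries. For the share, the exact permutation test of the double mutant against Xlf-/- could not go below p = 0.1. The minus-strand bin 2816 to 2825, which holds the precise prey end as aligned, took 84.0% of wild-type, 80.1% of PQR, 53.2% of Xlf-/- and 12.6% of PQR Xlf-/- substrate junctions. Its log2 fold was -0.66 for Xlf-/- over wild type (edgeR adjusted p = 0.0016; not called without wild-type library 1, -0.64, or Xlf-/- library 2, -0.50). It was -2.08 for the double mutant over Xlf-/- (edgeR adjusted p = 1.1e-10). The PQR effect there differed with XLF status (difference of log2 folds -2.02, edgeR adjusted p = 1.6e-07), the 1 bin of 59 called in that test. That count was 1 with TMM scaling, 3 with DESeq2 (2 higher, 1 lower), 3 without wild-type library 1, and 2 without PQR library 1 or Xlf-/- library 2. Position 2817 on the minus strand, the most used, took 79.0% ± 2.31 (SD, n = 2), 75.1% ± 2.83 (SD, n = 3), 45.6% ± 8.49 (SD, n = 2) and 8.19% ± 1.54 (SD, n = 3). Trimmed prey rose: bin 2756 to 2765 on the minus strand held 0.00334% of wild-type (1 junction), 0.303% of Xlf-/- and 3.77% of PQR Xlf-/- junctions. It rose in the double mutant over Xlf-/- (log2 fold 3.65, edgeR adjusted p = 0.0030), a call lost without Xlf-/- library 1 (log2 fold 3.06). Plus-strand bin 2866 to 2875 was at 0 of 46148 wild-type junctions, which allows up to 0.0065%, and at 0.214% in Xlf-/- (edgeR adjusted p = 0.00027).

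Between Xlf-/- and wild type 21 of 59 signal-join bins differed (18 higher, 3 lower). There were 22 with TMM scaling (16 higher, 6 lower) and 24 with DESeq2 (16 higher, 8 lower). Between the double mutant and Xlf-/- 22 differed (19 higher, 3 lower), with 11 under TMM scaling (2 higher, 9 lower) and 17 by DESeq2 (10 higher, 7 lower). That count fell to 1 without Xlf-/- library 1, and to 11 without Xlf-/- library 2 or double-mutant library 2. Between PQR and wild type edgeR called 0 bins, with 14 at an unadjusted p under 0.05. DESeq2 called 8, all lower. In the opposite direction, edgeR called 2, both higher, with no count filter and 1, higher, without PQR library 3.

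In class switching, the bait break in Sμ is joined to breaks in a downstream switch region, and anti-CD40 with IL-4 directs switching to IgG1 and IgE. Where Sμ broke and rejoined nearby, junctions stay within Sμ. On chromosome 12 (mm9 positions), the Sμ junctions lay from 114661500 to 114671496, those of Sγ1 from 114558030 to 114587987 and those of Sε from 114507055 to 114516995. Xlf-/- cells had a smaller share of junctions in both acceptor regions and a larger share in Sμ. Sγ1 held 63.3% ± 1.93 (SD, n = 3) of wild-type IgH junctions and 56.4% ± 1.04 (SD, n = 4) of Xlf-/- junctions. Sε fell from 15.6% ± 2.79 (SD, n = 3) to 5.20% ± 0.464 (SD, n = 4). Sμ rose from 20.3% ± 1.12 (SD, n = 3) to 33.9% ± 0.532 (SD, n = 4), and the rest of IgH rose from 0.696% ± 0.476 (SD, n = 3) to 4.47% ± 0.753 (SD, n = 4). In PQR the shares were 64.3% ± 1.40, 15.0% ± 3.09, 19.9% ± 1.65 and 0.682% ± 0.0442 (SD, n = 2 each), in the order Sγ1, Sε, Sμ and the rest. In PQR Xlf-/- they were 56.0% ± 1.30, 4.46% ± 0.823, 35.1% ± 0.635 and 4.45% ± 0.156 (SD, n = 3 each).

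The XLF effects over all 12 libraries were -7.61 points for Sγ1, -10.5 for Sε, 14.4 for Sμ and 3.77 for the rest of IgH. Each gave p = 0.00286, the smallest that the exact two-sided permutation test allows, with an adjusted p of 0.00571 over 14 tests. In each region all 7 Xlf-deficient libraries lay on 1 side of all 5 others. Within run 1 they were -6.60, -11.7, 14.7 and 3.55 points, each with exact permutation p = 0.0333, the smallest allowed there. Between Xlf-/- and wild type alone each region gave the smallest exact p, 0.0286, and an adjusted p of 0.0750 over 21 tests. These comparisons pass 0.05 by the unadjusted p alone, and leaving out any 1 of these 7 libraries ends that, since the smallest p then exceeds 0.05.

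No PQR effect on region shares passed the test over all libraries. The effects were 0.274 points for Sγ1 (exact two-sided permutation p = 0.754), -0.660 for Sε (p = 0.537), 0.401 for Sμ (p = 0.529) and -0.0146 for the rest of IgH (p = 0.954). Within run 1 the last was 0.382 points with p = 0.0333, and the others had exact p from 0.367 to 0.8. Sμ in the double mutant lay 1.19 points above Xlf-/- (exact two-sided permutation p = 0.0286, adjusted p = 0.0750 over 21 tests). It passed 0.05 by the unadjusted p alone. Without any 1 of the 7 libraries the difference was 0.847 to 1.47 points, with exact permutation p from 0.0667 to 0.133. The smallest p allowed then exceeds 0.05, so these refits could not pass. With distinct positions the difference was 0.699 points (exact permutation p = 0.257).

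**Figure D4:**
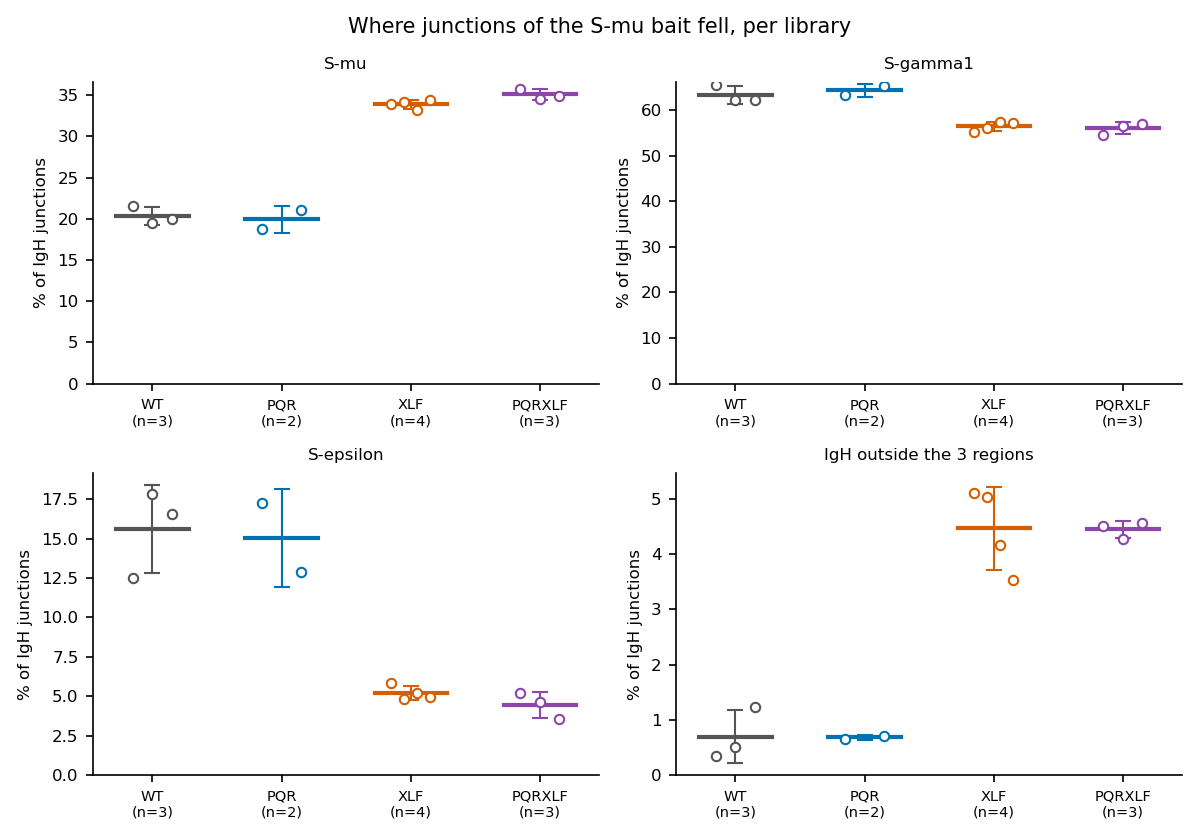
Share of IgH junctions in Sμ, Sγ1, Sε and the rest of IgH, per library in percent; circles are libraries, bars are genotype means and whiskers are SD. Wild-type and PQR libraries lie apart from Xlf-/- and PQR Xlf-/- libraries in all 4 panels.

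Bins of 500 bp placed these changes. The 5 bins with the largest fall in Xlf-/- all lay in Sε on the deletional strand, such as 114514501 to 114515000, from 3.22% to 0.705% of junctions (log2 fold -2.23, edgeR adjusted p = 6.3e-13), and 114515001 to 114515500, from 2.46% to 0.501% (log2 fold -2.31, edgeR adjusted p = 2.4e-12). The bins with the largest rise lay in Sμ and Sγ1. Sμ bin 114661501 to 114662000 on the deletional strand was at 0 of 22625 wild-type junctions, which allows up to 0.0133%, and at 0.318% in Xlf-/- (edgeR adjusted p = 2.2e-09). Sγ1 bin 114581001 to 114581500 in the inverted orientation was also at 0 in wild type and at 0.0953% in Xlf-/- (edgeR adjusted p = 1.2e-05). In all 75 of 116 bins differed (50 higher, 25 lower), 76 with TMM scaling (43 higher, 33 lower), 73 with DESeq2 (45 higher, 28 lower) and 70 within run 1, where wild type has 1 library, assumed to vary like the other groups. edgeR called 0 bins between PQR and wild type (9 at an unadjusted p under 0.05, 0 by DESeq2). It called 0 between the double mutant and Xlf-/- (14 unadjusted, 4 by DESeq2, 4 without Xlf-/- library 4), and 0 for the difference of the PQR effect between XLF states (17 unadjusted, 12 by DESeq2). The most used single positions were Sμ 114669184 on the plus strand (0.0719% ± 0.0302, SD, n = 3, in wild type) and Sγ1 114575292 and 114572698 on the minus strand, the highest genotype mean being 0.0859% at 114575292 in PQR.

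Switch junctions without XLF shared more bases. Microhomology of 4 bp or more was found in 9.65% ± 0.439 (SD, n = 3) of wild-type Sγ1 and Sε junctions, 9.35% ± 0.223 (SD, n = 2) in PQR, 23.4% ± 1.85 (SD, n = 4) in Xlf-/- and 24.7% ± 0.896 (SD, n = 3) in PQR Xlf-/-. Direct junctions, with neither overlap nor insertion, were 23.5% ± 0.262 (SD, n = 3), 25.0% ± 0.869 (SD, n = 2), 8.37% ± 1.32 (SD, n = 4) and 6.46% ± 0.225 (SD, n = 3). Inverted junctions in Sγ1 were 8.24% ± 0.870 (SD, n = 3), 6.60% ± 0.0156 (SD, n = 2), 15.7% ± 2.40 (SD, n = 4) and 18.8% ± 1.82 (SD, n = 3). The XLF effects were 14.6, -16.8 and 9.86 points, each with p = 0.00286, the smallest that the exact two-sided permutation test allows, and adjusted p = 0.00571 over 14 tests. All 7 Xlf-deficient libraries lay on 1 side of all 5 others in each. Within run 1 they were 14.8, -17.3 and 10.2 points (exact permutation p = 0.0333, the smallest allowed). Between Xlf-/- and wild type alone the differences were 13.8, -15.1 and 7.50 points (exact permutation p = 0.0286, the smallest allowed, adjusted p = 0.0750), past 0.05 by the unadjusted p alone, which ends without any 1 library because the smallest p then exceeds 0.05.

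The PQR effects on the same shares were 0.513 points for microhomology (exact two-sided permutation p = 0.486), -0.187 for direct joins (p = 0.8) and 0.723 for inversion (p = 0.529). Between the double mutant and Xlf-/- the differences were 1.33 points (exact two-sided permutation p = 0.314), -1.91 points (p = 0.0857) and 3.09 points (p = 0.114), with 0.0286 the smallest p allowed. Between PQR and wild type they were -0.304 points (exact permutation p = 0.5), 1.54 points (p = 0.1) and -1.64 points (p = 0.2), with 0.1 the smallest allowed.

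**Figure D5:**
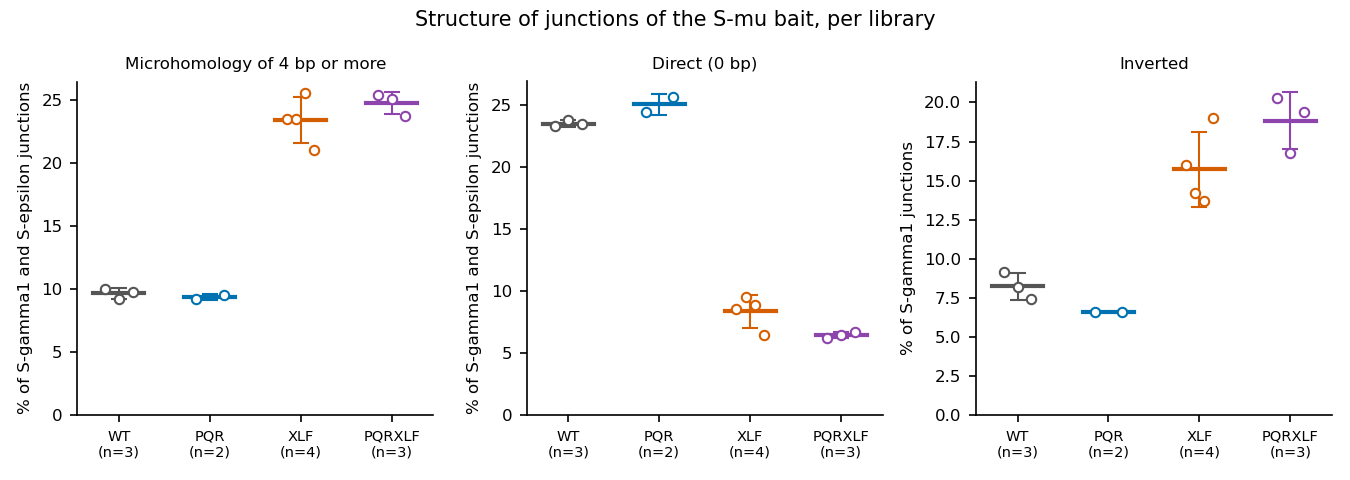
Switch junctions with microhomology of 4 bp or more, direct switch junctions, and inverted Sγ1 junctions, per library in percent; circles are libraries, bars are genotype means and whiskers are SD. Microhomology lies between 21.0 and 25.6% in Xlf-/- libraries and between 9.17 and 10.0% in wild-type libraries.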

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

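On precise signal joins, the tests of far bait ends and of the leading chromosome, the reading of the 3 bp tolerance as a test of alignment, and all tests of junctions on chromosome 6 and of distal junctions were chosen only after the results were seen. The 4 Xlf-/- CSR libraries were the 1 group large enough for a ratio of gap to range, which no library passed in depth or in 7 shares, a test with little power at 4. Over bins, library 4 differed from libraries 1, 2 and 3 with chi-square 3.97, 5.20 and 2.64 times its degrees of freedom, against 1.47 to 1.75 among those 3. It had 15.7% of its junctions outside IgH, against 8.59 to 10.1%. Without it, 74 bins differed between Xlf-/- and wild type (75 with it) and 4 between the double mutant and Xlf-/- (0 with it).

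The PQR effect differed between cells with and without XLF at 3 bins, by the interaction term of the edgeR fit. In signal joins the bin that holds the precise prey end had a difference of log2 folds of -2.02, counted on the same junctions as the precise joins. Precise joins differed by -36.7 points between the double mutant and Xlf-/-. Joins whose bait end lay far from the signal end, which are never precise, differed by -7.53 points between the same genotypes, all 3 double-mutant libraries below both Xlf-/- libraries, and allowing up to 3 bp of loss gave -41.7 points, which argues against both as the source of the fall. What stays open is the cell line behind each genotype: both Xlf-/- libraries shared 1 leading chromosome outside the substrate, apart from chromosome 6, so genotype and line cannot be told apart there, while the 3 double-mutant signal-join libraries had 3 different ones (in library 1 the same chromosome 1 as in Xlf-/-, in library 2 with 241 of 3174 junctions) and the 2 wild-type libraries 1. The genotype itself also stays open, and was not tested apart from the line.

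In coding joins the difference of log2 folds was -2.38 at minus-strand bin 2806 (10 bp) and -4.65 at minus-strand bin 1047 to 1146. The second rests on 1 double-mutant junction, and DESeq2 called neither.

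Junctions on chromosome 6, outside the substrate, lay above wild type in the Xlf-deficient genotypes of both substrate assays, and in PQR from the coding-end bait. From the coding-end bait they were 2.73% ± 1.04 (SD, n = 2) of all junctions in wild type, 5.22% ± 1.23 (SD, n = 3) in PQR, 31.1% ± 16.4 (SD, n = 2) in Xlf-/- and 18.0% ± 5.93 (SD, n = 2) in PQR Xlf-/-, an XLF effect of 20.6 points (exact two-sided permutation p = 0.0167, the smallest allowed, adjusted p = 0.0561 over 36 tests). From the signal-end bait they were 0.341% ± 0.0505 (SD, n = 2) in wild type, 0.549% ± 0.278 (SD, n = 3) in PQR, whose libraries overlapped wild type, 2.74% ± 1.84 (SD, n = 2) in Xlf-/- and 1.95% ± 0.690 (SD, n = 3) in PQR Xlf-/-, an XLF effect of 1.90 points (same p and adjusted p).

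The authors' deposited sheets give, for each library and switch region, the share of distal junctions. The cut was inferred by taking the lowest positions of each library as distal. All libraries then fitted 1 cut per region, with distal junctions at or below 114665100 in Sμ, 114565999 in Sγ1 and 114513000 in Sε. In Sμ they were 3.43% ± 1.84 (SD, n = 3) of the region's junctions in wild type, 3.87% ± 0.478 (SD, n = 2) in PQR, 19.8% ± 4.16 (SD, n = 4) in Xlf-/- and 18.4% ± 1.76 (SD, n = 3) in PQR Xlf-/-. In Sγ1 they were 0.114% ± 0.0989 (SD, n = 3) in wild type, 0.205% ± 0.0329 (SD, n = 2) in PQR, 2.10% ± 0.171 (SD, n = 4) in Xlf-/- and 2.55% ± 0.317 (SD, n = 3) in PQR Xlf-/-. In Sε they were 4.60% ± 0.534 (SD, n = 3) in wild type, 5.26% ± 1.61 (SD, n = 2) in PQR, 17.9% ± 2.23 (SD, n = 4) in Xlf-/- and 24.2% ± 1.27 (SD, n = 3) in PQR Xlf-/-. PQR differed from wild type by 0.448 points in Sμ (exact two-sided permutation p = 0.7), 0.0912 in Sγ1 (p = 0.4) and 0.661 in Sε (p = 0.6). The smallest p allowed there is 0.1. The XLF effects were 15.4, 2.17 and 16.1 points, each with exact two-sided permutation p = 0.00286, the smallest allowed, and adjusted p = 0.0206 over 36 tests. A share within a region can also rise because the rest of that region fell. Sε fell from 15.6% of IgH junctions in wild type to 5.20% in Xlf-/-. Its distal share therefore does not show that distal Sε joins became more common among all junctions.

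For the 75 CSR bins that differed between Xlf-/- and wild type, 1 of the 35 splits of the 7 libraries, the real one, gave as many. The highest of the others gave 17. No fewer splits are possible with 7 libraries, so chance is made unlikely but is not excluded. The splits do not separate genotype from sequencing run or from the source of the libraries. For the double mutant against Xlf-/- the real split gave 0 bins by edgeR (14 at an unadjusted p under 0.05, 4 by DESeq2), so each of the 35 splits had to give as many (35 of 35, the highest other 0), and the splits decide nothing.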

How the results depend on the processing

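Over 77 results, 65 shares and 12 counts of bins, there were 507 refits other than leaving out a library. Of these, 410 were unchanged, 40 lost the threshold, 1 gained it, 20 moved a count by more than 1.5 times and 36 changed sign. For a share, unchanged means the same direction and side of the threshold. For a count of bins it means only a total within 1.5 times. Higher and lower bins were not compared there, so some unchanged counts shifted between higher and lower. Sign changes were in differences that had not passed their test in the main setting. The fits without far bait ends, within 1 sequencing run, with the run as a covariate, and with gaps over all IgH junctions were chosen after seeing the data. Counting region shares over the 3 switch regions, switch junctions without insertions, gaps over all IgH junctions, and the authors' second coding deletion sheet changed no direction and no call. Of 272 such refits of the named bins, 237 kept the call, 35 lost it and 0 changed sign. Of 256 with a library left out, 201 kept it, 55 lost it and 0 changed sign. For shares a call here is an unadjusted exact p under 0.05. Depth limits the coding-join assay most, where a count of 0 in wild type allows up to 0.124%. Alternatives for signal-join microhomology were not run, since gaps came only pooled. Where nothing else is said the cause was not tested.

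The PQR difference from wild type in prey-end loss over 20 bp, 0.617 points, became -2.16 points at 50 bp, -1.46 with distinct positions, -0.539 with the authors' deletion sheet, -0.152 with pooled junctions and -5.74 within run 1. At the bait end it turned from -3.02 to 0.349 points at 10 bp and 0.686 within run 1. For coding microhomology it turned from 2.53 to -3.66 points without insertions, where the XLF effect was 0.233 points. With a 4 bp minimum that XLF effect was 1.22 points, and the PQR effect was 0.0103 on the logit scale. Within run 1 the XLF effects lost their calls, since fewer libraries cannot reach 0.05: 31.6 points for prey-end loss, 32.4 for bait-end loss, 9.13 for microhomology and -9.90 for junctions at the coding ends. For signal joins, a tolerance of 3 bp gave 0.0355 points for PQR against wild type and a PQR effect of -20.9 points that no longer passed. For signal-join loss, the 50 bp threshold gave -0.110 points for Xlf-/- against wild type, -0.414 for the PQR effect and 3.83 for the XLF effect. Without far bait ends, PQR against wild type was 1.62 points and the PQR effect was 16.2 points with exact permutation p = 0.01. Every join left out counts as loss over 20 bp and their share differs by genotype, so the filter itself shifts both values. Whether the shares with or without these joins compare the genotypes better was not tested, and no conclusion is drawn.

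In the CSR assay, distinct positions gave -0.788 points for PQR against wild type in Sγ1, 0.378 for the double mutant against Xlf-/-, and -0.205 for the PQR effect. In Sμ they gave 1.28 points for PQR against wild type and 0.699 for the double mutant against Xlf-/-, no longer past the threshold. That Sμ difference was 1.53 points over all junctions, 0.0528 on the logit scale and 1.30 points within run 1, none past it. Run 1 holds too few libraries for that difference to pass. Over all junctions the double mutant differed from Xlf-/- by 0.335 points in Sγ1 and 0.0280 outside the 3 regions, where the PQR effect was 0.00736. Outside the regions, pooled junctions gave 0.0786 points for PQR against wild type, 0.0568 for the double mutant against Xlf-/- and 0.0677 for the PQR effect. The logit scale gave 0.117, 0.00731 and 0.0622 for the same, and run 1 gave 0.167, 0.597 and 0.382 points, the last past the threshold there (exact permutation p = 0.0333). The PQR effect on inversion was -0.00776 on the logit scale. Within run 1, PQR against wild type was 0.458 points in Sμ and 0.179 for microhomology, which was 0.935 with a 2 bp minimum, and the PQR effect on direct joins was 0.0159. Differences between Xlf-/- and wild type within run 1 could not pass 0.05 with so few libraries: -4.87 points for Sγ1, -12.8 for Sε, 14.3 for Sμ, 3.34 for the rest of IgH, 14.1 for microhomology, -16.1 for direct joins and 8.18 for inversion.

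The labels give no source for a pairing by replicate number. In coding joins and CSR same-numbered libraries correlated from below 0 to above it, such as -0.243 for coding-join wild-type and PQR library 1 and 0.442 for Xlf-/- and double-mutant library 1. In signal joins the pairs of wild type with Xlf-/- (2 pairs, 1 separate value) and of PQR with the double mutant correlated above 0.1, and each PQR and double-mutant library correlated best with its own number among those of the other genotype (0.473, 0.196 and 0.293). Pairs of wild type with PQR (-0.119 and -0.281) did not, nor did 1 of the 2 pairs of Xlf-/- with the double mutant (0.233 and -0.144). In the 2 genotypes with 3 signal-join libraries the share outside the substrate also differed by number: 13.2%, 8.87% and 4.08% in PQR libraries 1, 2 and 3, and 18.9%, 8.73% and 5.28% in the double mutant, so signal-join libraries of 1 number are not shown to be unrelated. With the replicate number as a block, sign flips over so few pairs cannot reach 0.05, and the XLF effects were 37.6 points for prey-end loss, 34.0 for bait-end loss, -12.7 for junctions at the coding ends, -51.7 for precise signal joins and 17.4 for signal-join loss. The blocked PQR effect on precise signal joins was -19.6 points, and PQR against wild type was -1.20 points for prey-end loss and 0.256 outside the switch regions. Blocked CSR differences between Xlf-/- and wild type were -7.13 points for Sγ1, -10.3 for Sε, 13.4 for Sμ, 4.08 for the rest, 14.5 for microhomology, -14.5 for direct joins and 6.40 for inversion. The blocked XLF effects in the same order were -7.96, -10.2, 14.3, 3.90, 15.2, -16.6 and 9.17 points, and the double mutant differed from Xlf-/- in Sμ by 1.36 points. Blocked counts of signal-join bins were 4 for PQR against wild type (all higher), 40 for the double mutant against Xlf-/- (36 higher, 4 lower) and 3 for the difference of PQR effects (2 higher, 1 lower). The block moved no other count by more than 1.5 times.

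Counts of bins past the threshold moved as follows. TMM scaling gave 4 for the coding-join difference of PQR effects (2 in the main setting) and 11 for the double mutant against Xlf-/- in signal joins (22). Most of the latter bins were lower under TMM scaling and higher in the main setting. Bins of 2 times the width, which leaves fewer bins to test, gave 13 for coding-join Xlf-/- against wild type (24) and 8 for the double mutant against Xlf-/- (15). DESeq2 gave 11 for coding-join Xlf-/- against wild type (24), 6 for the coding-join difference of PQR effects (2), 8 for signal-join PQR against wild type (0), 3 for the signal-join difference (1), 4 for the CSR double mutant against Xlf-/- (0) and 12 for the CSR difference (0). The run as a covariate gave 7 for coding-join PQR against wild type (3), 23 for the double mutant against Xlf-/- (15) and 7 for the difference (2), with 1 Xlf-/- library and 1 wild-type library that the run term does not take up. Within run 1, coding-join PQR against wild type gave 5, with 1 wild-type library. No count filter gave 2 for signal-join PQR against wild type (both higher, where DESeq2's 8 were all lower), 2 for the signal-join difference and 3 for the CSR double mutant against Xlf-/-.

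Leaving out 1 library at a time gave these ranges. For prey-end loss PQR differed from wild type by -3.92 to 5.16 points (-3.92 without wild-type library 2, -1.20 without PQR library 3) and the XLF effect was 34.4 to 39.0 points. For bait-end loss PQR differed from wild type by -5.33 to -0.705 points and the XLF effect was 32.9 to 36.4 points. Both XLF effects lost their calls without PQR library 1, 2 or 3 (35.9, 36.5 and 37.6 points at the prey end, 34.4, 35.6 and 34.0 at the bait end), where the smallest p is 0.0556. For coding microhomology the XLF effect was 7.44 to 8.66 points over the 7 refits, and its adjusted p had not passed in the main setting. In none of these refits can the unadjusted p fall under 0.05. The effect was 7.96 and 8.14 points without wild-type library 1 or 2, and 8.10, 7.63 and 8.43 without PQR library 1, 2 or 3. It was 7.44 and 8.66 points without double-mutant library 1 or 2. At the coding ends PQR differed from wild type by -12.4 to 0.531 points (above 0 without wild-type library 2), the PQR effect was -7.81 to -1.35 (past the threshold without wild-type library 1, -7.81) and the XLF effect was -16.2 to -9.75, no longer past it without PQR library 1, 2 or 3 (-13.3, -13.0 and -12.7) or Xlf-/- library 1 (-12.1). For precise signal joins PQR differed from wild type by -9.25 to 0.589 points (above 0 without wild-type library 1), and the PQR effect was -24.1 to -17.0, no longer past the threshold without wild-type library 1 (-18.1), PQR library 3 (-19.9), Xlf-/- library 1 or 2 (-17.0 and -24.1) or double-mutant library 1, 2 or 3 (-20.2, -21.2 and -20.2). For signal-join loss PQR differed from wild type by -9.32 to 0.693 points (above 0 without wild-type library 2), Xlf-/- by -1.32 to 8.70 (-1.32 without wild-type library 1, -1.11 without Xlf-/- library 2), and the XLF effect was 14.8 to 19.9, no longer past the threshold without wild-type library 1 (14.8), PQR library 2 (16.8) or Xlf-/- library 2 (15.0). In coding joins, bins called were 0 to 3 for PQR against wild type (0 without wild-type library 2 or PQR library 2, 1 without PQR library 1), 15 to 21 for Xlf-/- (15 without wild-type library 1), 6 to 12 for the double mutant against Xlf-/- (6 without Xlf-/- library 1 or double-mutant library 2, 9 without double-mutant library 1) and 0 to 4 for the difference of PQR effects (0 without double-mutant library 2, 1 without Xlf-/- library 2 or double-mutant library 1, 4 without wild-type library 2). In signal joins they were 0 to 1 for PQR against wild type (1 without PQR library 3), 1 to 28 for the double mutant against Xlf-/- (1 without Xlf-/- library 1, 11 without Xlf-/- library 2 or double-mutant library 2) and 1 to 3 for the difference (3 without wild-type library 1, 2 without PQR library 1 or Xlf-/- library 2). In CSR they were 0 to 4 for the double mutant against Xlf-/- (4 without Xlf-/- library 4).

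For CSR shares, leaving out 1 library ended each pairwise call, by unadjusted p, of Xlf-/- against wild type, since the smallest p then exceeds 0.05. The ranges were -7.50 to -5.79 points for Sγ1, -12.0 to -9.32 for Sε, 13.1 to 14.2 for Sμ, 3.55 to 4.08 for the rest, 13.0 to 14.5 for microhomology, -15.5 to -14.5 for direct joins and 6.40 to 8.18 for inversion. The XLF effects over all 12 CSR libraries kept direction and call in every such refit. PQR differed from wild type by -0.00433 to 2.10 points in Sγ1 (below 0 without PQR library 2), -2.77 to 1.61 in Sε (0.530 without wild-type library 2, 1.61 without PQR library 2), -1.56 to 0.776 in Sμ (0.241 without wild-type library 1, 0.776 without PQR library 1) and -0.194 to 0.256 in the rest (0.256 without wild-type library 3, 0.0170 without PQR library 1). The PQR effect was -0.221 to 0.83 points in Sγ1 (-0.0231 without wild-type library 2, -0.221 without PQR library 2), -1.75 to 0.433 in Sε (above 0 without PQR library 2), -0.182 to 0.985 in Sμ (below 0 without PQR library 2), -0.169 to 0.120 in the rest (0.120 without wild-type library 3, 0.00107 without PQR library 1, 0.0936 and 0.0811 without Xlf-/- library 1 or 2, 0.0298 without double-mutant library 2) and -0.502 to 0.120 for direct joins (0.120 without PQR library 1, 0.0102 without Xlf-/- library 2). Switch microhomology kept its sign in every refit, at -0.545 to -0.116 points for PQR against wild type, 0.121 to 0.874 for the PQR effect and 0.546 to 2.05 for the double mutant against Xlf-/-. The double mutant differed from Xlf-/- by -0.894 to 0.309 points in Sγ1 (above 0 without double-mutant library 1). In the rest it differed by -0.325 to 0.201 (0.201 and 0.177 without Xlf-/- library 1 or 2, 0.0738 without double-mutant library 2). In Sμ it differed by 0.847 to 1.47 points, past the threshold in none of these refits, since the smallest p then exceeds 0.05.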

Other observations

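The tests of depth and run on switch microhomology and of the positions on chromosome 6 and on the leading chromosome were chosen only after the results were seen. Those on joins across the bait cut were fixed before their results were seen. Inverted junctions in Sμ and Sε, inserted bases in switch junctions and junctions outside IgH were not planned comparisons. They count as classes chosen after their values were seen.

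The share of inverted junctions within a region changed with XLF status in the other switch regions too. Inverted junctions in Sμ were 20.4% ± 1.82 (SD, n = 3) in wild type, 20.0% ± 2.37 (SD, n = 2) in PQR, 31.8% ± 1.47 (SD, n = 4) in Xlf-/- and 31.5% ± 0.720 (SD, n = 3) in PQR Xlf-/-. In Sε they were 6.06% ± 1.77 (SD, n = 3), 4.61% ± 1.32 (SD, n = 2), 15.1% ± 3.22 (SD, n = 4) and 22.7% ± 1.84 (SD, n = 3). The XLF effects were 11.4 and 13.6 points, each with the smallest exact two-sided permutation p allowed, 0.00286, and adjusted p = 0.0206 over 36 tests. Sε itself fell from 15.6% of IgH junctions in wild type to 5.20% in Xlf-/-, with the largest falls in deletional bins. The shares within Sε, for inverted and for distal junctions, thus do not show that such joins became more common among all junctions. In Sε all 3 double-mutant libraries lay above all 4 Xlf-/- libraries for inversion (7.61 points, exact permutation p = 0.0571) and for distal junctions (6.27 points, p = 0.0286, the smallest allowed). The PQR effect on distal Sε junctions over all libraries was 3.47 points (exact permutation p = 0.00857, adjusted p = 0.0514). Inserted bases in switch junctions were 19.2% ± 4.10 (SD, n = 3), 15.2% ± 2.35 (SD, n = 2), 19.3% ± 3.40 (SD, n = 4) and 21.1% ± 0.879 (SD, n = 3), with an XLF effect of 3.01 points (exact permutation p = 0.146). Junctions outside IgH were 6.59% ± 4.22 (SD, n = 3), 5.46% ± 0.297 (SD, n = 2), 10.8% ± 3.33 (SD, n = 4) and 9.52% ± 1.78 (SD, n = 3), with an XLF effect of 4.14 points (exact permutation p = 0.0314, adjusted p = 0.0800).

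Joins of a coding end back across its own cut differed by 13.0 points between the double mutant and Xlf-/-. Counting each pair of positions once gave 13.0 points (12.9782 before rounding), with every double-mutant library above every Xlf-/- library, which argues against repeated molecules as the cause. Within run 1, which held 1 Xlf-/- and 1 double-mutant library, the difference was 12.3 points. Those libraries share their run, but with 1 per genotype the genotype cannot be told apart from variation between libraries. No conclusion on the run is drawn from them. These joins cover only rejoining that altered the sequence. The genotype itself stays open, untested.

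The rise in switch microhomology without XLF held within 1 sequencing run (14.8 points, exact two-sided permutation p = 0.0333, the smallest allowed), which argues against the run as its source. Between libraries of matched depth, from 9624 to 14119 junctions, the mean was 9.29% in 3 libraries with XLF and 24.9% in 4 without, a difference of 15.6 points (exact two-sided permutation p = 0.0286, the smallest allowed), which argues against depth. Why microhomology rose was not tested further.

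For PQR library 3 and Xlf-/- library 1 of the coding-join assay, positions outside the substrate were used. Of their chromosome 6 junctions, 90.7% (88 of 97) and 95.7% (749 of 783) lay between the outermost Igk segments of the GRCm38.p6 table, and 34.0% and 31.4% between 1 kb before the first and 1 kb past the last Jκ segment. The rise on chromosome 6 may be joining of substrate ends to RAG breaks at Igk, the immunoglobulin κ light-chain locus.

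Outside the substrate, chromosome 2 led in both wild-type coding-join libraries (1729 of 2512 and 503 of 751 junctions), and their chromosomes did not differ past the threshold (chi-square 28.1 on 19 degrees of freedom). In PQR library 3 chromosome 11 led, with 88.7% of its junctions within 100 kb of their median, and in Xlf-/- library 1 chromosome 1 led after chromosome 6, with 72.2% within 100 kb, on both strands. The leading chromosome is a candidate site of substrate integration. If so, the 2 wild-type libraries may be 1 line, and so may the 2 Xlf-/- libraries, which share chromosome 1. Apart from chromosome 6, wild-type, PQR and Xlf-/- libraries of 1 number shared their leading chromosome between the 2 substrate assays. It was 2 in wild type, 1 in Xlf-/-, and 5 (82 of 1003 and 158 of 1889 junctions), 7 and 11 in PQR. In the double mutant, coding-join library 2 and signal-join library 3 shared chromosome 10. The 2 assays may thus have read the same lines, and are not shown to be independent.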
